A study of Mus musculus with 59 samples.

How the data were processed

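The data are single-cell RNA-seq profiles of 59 mouse cells that the labels call chemical-induced neurons, all with an age label of 12 weeks. Per the labels' protocol, the content of each cell was drawn into a patch pipette in the living brain and moved into lysis buffer, and libraries were read on an Illumina HiSeq instrument. The labels put all cells in 1 group and name no animal, so the 59 cells were treated as 1 sample, and no control neurons, astrocytes or untreated cells were analysed here.

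The authors deposited 1 table of FPKM (fragments per kilobase of exon, scaled to the number of mapped fragments), with 1 column per cell. STAR 2.5.3a, featureCounts 1.5.3 and the mouse genome build GRCm38 are named in the submitters' processing notes. The annotation release, the strandedness of the counting and the treatment of multi-mapped reads are not given in the sources used here. Reads of near-identical copies, of overlapping genes and of antisense partners could therefore be split in ways that cannot be checked, which applies to ferritin, ubiquitin, actin and haemoglobin genes and to the ribosomal RNA gene Rn18s-rs5. The table holds 20740 features, of which 51 are ERCC spike-ins (synthetic RNAs added in known amounts) and 20689 are genes, 33 of them mitochondrial. 245 genes were at 0 in every cell, and 20168 reached an FPKM of 1 in at least 1 cell. Symbols were used as the table gives them, and 19393 of them were also found in a reference table of mouse gene names. Coordinates are those of GENCODE release M21 on GRCm38, which was used here and need not be the release behind the deposited values.

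Depth per cell was estimated from the deposited FPKM. Within a cell, FPKM multiplied by exon length is a whole multiple of what 1 fragment is worth, so the spacing of the low values gives the number of fragments behind the FPKM. Exon lengths came from GENCODE M21 for 19366 genes (93.6%). Over values up to 20 fragments, a median of 73.3% (64.1 to 79.9%) came out whole within a tolerance of 0.02 fragments. The remainder did not, so the values were kept as FPKM and no count model was used. The recovered fragments named below are these multiples rounded to whole numbers, so those of the remainder are approximate. The estimated depth had a median of 912996 fragments per cell, with quartiles of 326869 and 1645640 and a range of 29043 to 2950400. In 31 of the 59 cells a single fragment in a gene of 1 kb already gives an FPKM above 1, so detection at this threshold can rest on 1 fragment. ERCC spike-ins held a median of 3.70% (0.094 to 37.6%) of the summed FPKM, which is a share of FPKM and not of reads, and they were left out of gene counts and gene lists.

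A gene was called detected in a cell at an FPKM of 1 or more. Log2 values are log2(FPKM + 1), a scale on which differences between low genes are understated. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error over cells only and not differences between animals. Because there is 1 group, no test between groups was run and no p-value was computed. Before the data were examined, 31 gene lists with 336 genes were fixed, of which 320 were in the table. The neuronal list was compared with each other cell-type list within each cell as the difference of the mean log2(FPKM + 1). The spread of a gene was its SD over cells minus the running median of 501 genes sorted by mean, among the 8042 genes detected in at least 12 cells. Pairwise Spearman correlations between cells used the same genes and describe the profiles without a p-value.

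Genes were named by a rule set before the data were examined. It takes from each fixed list the members with the highest and lowest detection and those needed for joint counts, at most 8 per list. It also takes the 20 genes with the highest median FPKM, leaving out mitochondrial genes, and the 20 genes with the largest spread over the trend. Any gene named outside this rule is marked as such, and a few genes the rule takes are not reported here.

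Alternatives set beforehand were a detection threshold of any FPKM above 0 or of 5, rescaling each cell to a sum of 1000000, leaving out mitochondrial genes, keeping the 46 cells with at least 2000 genes, pseudocounts of 0.1 and 10, list medians in place of means, and no filter on low genes. A threshold of 10 recovered fragments, the 39 cells with at least 500000 fragments, and an astrocyte list without 4 genes were added after the data had been seen. The steps were tested on simulated data with 19366 genes and 59 cells. The estimated depth was recovered and 0 detection calls differed. Both outcomes were fixed by the simulation, which used the same exon lengths and the same detection formula, so they check the code and not the real values. Of 200 genes made over-dispersed, 162 (81%) were among the 200 with the largest spread. The size of their excess spread was set in the simulation and they were drawn from the more highly expressed genes. This share therefore does not measure how well the ranking performs on the real values. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No cell and no column was left out of the main values.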

Results

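Transcriptomes of 59 single mouse cells, which the labels call chemical-induced neurons in a study of turning astrocytes into neurons in the living brain, were examined for the genes they expressed. The cells form 1 group with an age label of 12 weeks and no animals are named, so each value describes these cells and has no biological replicate. Percentages are given with exact Clopper-Pearson 95% intervals, which cover counting error over cells only.

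Rn18s-rs5, a ribosomal RNA gene, had the highest median of all genes ranked, 94737 FPKM, in a ranking that left out mitochondrial genes. It was followed by Fth1 (ferritin heavy chain) at 14244 FPKM, Tmsb4x (an actin-binding thymosin) at 1901 FPKM and Ubb (polyubiquitin) at 1293 FPKM. The lipid carrier gene Apoe (1244 FPKM), the calmodulin gene Calm2 (1198 FPKM), the immediate early gene Fos (1160 FPKM) and the actin regulator Cfl1 (1129 FPKM) came next. Ftl1, Ckb, Sepw1, Cst3, Actb, Itm2b, Cox8a, Mt1, Eef1a1, Lars2, Cox6a1 and 1 ribosomal protein gene filled the remaining places among the 20 highest genes. The 50 highest genes of a cell held a median of 56.9% of its summed gene FPKM (23.9 to 87.9%), and mitochondrial genes held 7.62% (0.737 to 42.6%).

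The number of genes detected at an FPKM of 1 or more varied widely. The median was 3984 genes per cell, with quartiles of 2091 and 5654.5 and a range of 475 to 10310. At least 2000 genes were detected in 46 cells, and fewer than 1000 in 3 cells. Estimated depth ran from 29043 to 2950400 fragments per cell with a median of 912996.

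**Figure D1:**
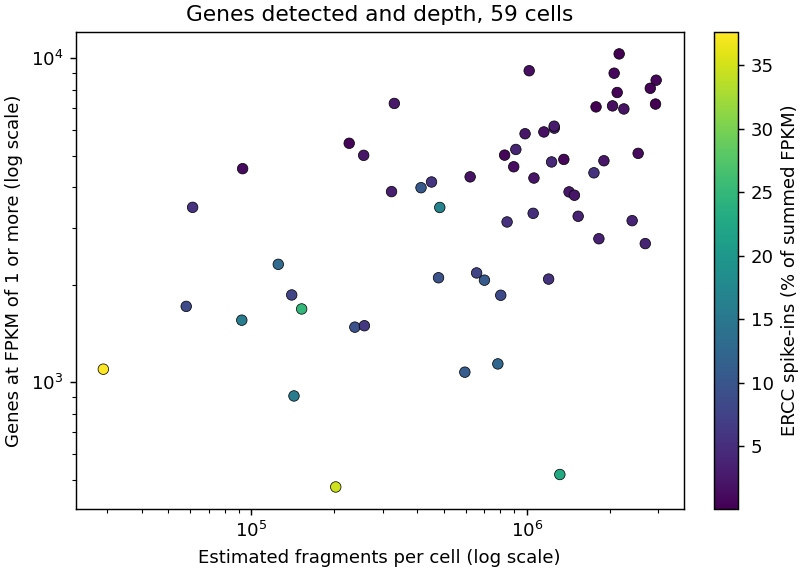
Genes detected at an FPKM of 1 or more (y axis, log scale) against estimated fragments (x axis, log scale), with 1 point for each of the 59 cells and colour for the ERCC share of summed FPKM in percent. Cells run from 475 to 10310 genes, and the ERCC share reaches 37.6%.

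Pan-neuronal genes were widely detected, at a level of detection far above that of genes from other organs. Of the 21 neuronal genes, 20 were detected in at least 50% of the cells, and the median gene was found in 76.3% of cells. Snap25, a synaptic vesicle fusion gene on chromosome 2 (136713453 to 136782428, GRCm38), was detected in 54 of 59 cells (91.5%, interval 81.3 to 97.2%) with a median of 136 FPKM. Uchl1 (a neuronal deubiquitinase) and the long non-coding RNA Meg3 were each detected in 52 cells. The lowest members were Nefh (neurofilament heavy chain) in 27 cells, Elavl4 in 35, Thy1 in 40, and Rbfox3 (which encodes NeuN) and Stmn2 in 41 each. At least 50% of the list was detected in 46 cells (78.0%, interval 65.3 to 87.7%), and 1 cell had no member of it. The off-tissue control list, made of genes of liver, pancreas, heart and other organs, had a median detection of 1.69% over 8 measured genes, with Myh6 the highest in 5 cells.

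Genes of immature neurons were detected in a minority of cells apart from 2 growth-related genes. Stmn1 (a tubulin-binding stathmin) was found in 53 cells and Gap43 (growth cone protein) in 46, while the median over the 13 measured members was 10.2% of cells. Cd24a, the next highest, was detected in 14 cells. Among the lowest, Neurod1 was detected in 5 cells, Eomes in 3, Insm1 in 2 and Nhlh1 in 1. Igfbpl1 was detected in 0 of 59 cells, for which the interval reaches 6.06%. Dcx, a migrating-neuroblast gene named outside the rule for named genes, was detected in 6 cells. Among 8 neural progenitor genes the median was 26.3% of cells, from Id3 in 23 cells to Nes in 2. Cell cycle genes had a median of 3.39% over 9 members, with Mcm2 the highest in 4 cells and Rrm2 in 0.

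**Figure D2:**
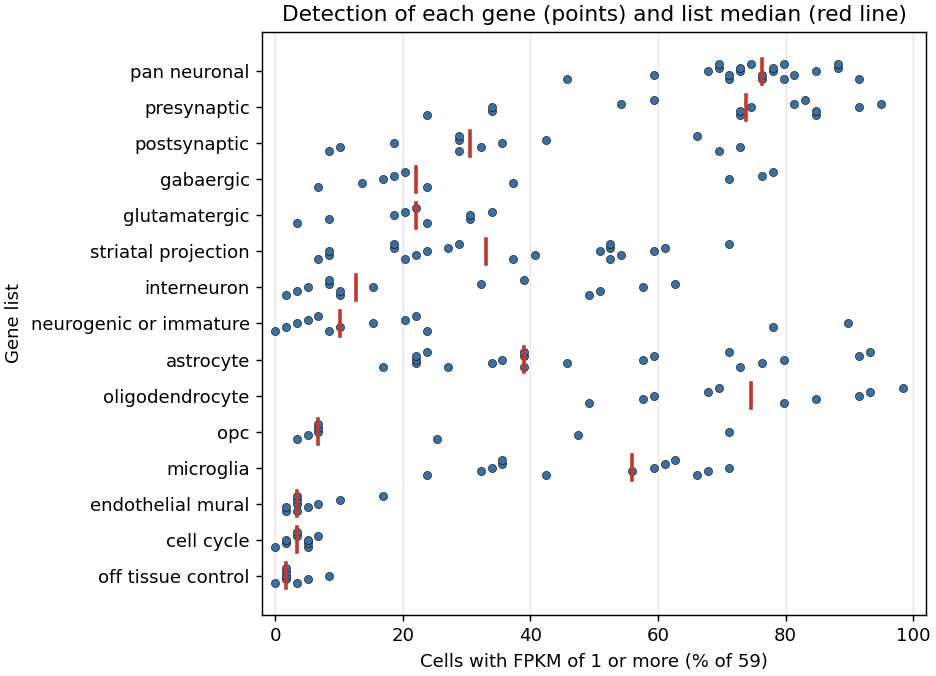
Percent of the 59 cells with an FPKM of 1 or more (x axis) for each gene, drawn as a point, in 15 fixed gene lists (y axis), with the list median as a red line. The neuronal median is 76.3%, the oligodendrocyte median 74.6% and the off-tissue control median 1.69%.

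Neuronal genes lay above astrocyte genes in most cells when the lists were compared within each cell. The mean log2(FPKM + 1) had a median over cells of 4.04 for the neuronal list and 2.56 for the astrocyte list. The within-cell difference had a median of 0.97 (quartiles -0.39 and 2.29, SD 1.95 over cells) and was above 0 in 39 of 59 cells (66.1%, interval 52.6 to 77.9%). Without Apoe, Glul, S100b and Clu, which other brain cell types also express, the neuronal list was higher in 51 cells (86.4%) with a median difference of 1.64. Those 4 genes were picked after their detection had been seen to be high, so a rise was built into that alternative. With a pseudocount of 10 the neuronal list was higher in 55.9% of cells with a median difference of 0.21. Different genes are compared here, so a sign shows which list had the higher mean level and not how much RNA of either cell type was present.

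Against other lists the neuronal genes took both positions. The neuronal list was higher than the oligodendrocyte list in 23 cells (39.0%, interval 26.5 to 52.6%), with a median difference of -1.35 and a range of -9.29 to 4.92. It was higher than the microglia list in 37 cells (62.7%, with a lower interval limit of 49.1%), with a median difference of 1.17. It was higher than the endothelial and mural list, the fibroblast and ependymal list, the erythroid list and the off-tissue list in 58 cells each. It exceeded the reactive astrocyte list and the immature neuron list in 55 cells each, the progenitor list in 54 and the oligodendrocyte precursor list in 53. Among the neuronal, astrocyte, oligodendrocyte and microglia lists, the highest mean was oligodendrocyte in 30 cells, neuronal in 18, microglia in 7 and astrocyte in 4.

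**Figure D3:**
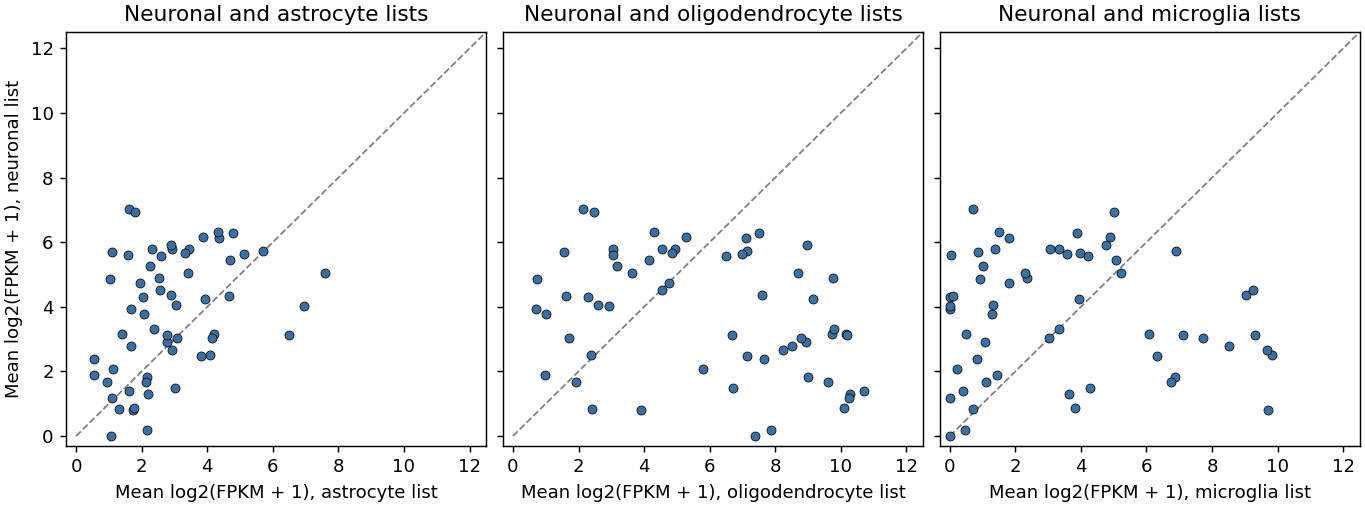
Mean log2(FPKM + 1) of the neuronal list (y axis) against that of the astrocyte, oligodendrocyte and microglia lists (x axes), with 1 point per cell and a dashed line where both are equal. The neuronal list is higher in 39, 23 and 37 of the 59 cells.

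Oligodendrocyte genes were detected about as widely as neuronal genes. Of 10 myelin and oligodendrocyte genes, 9 were found in at least 50% of cells, and the list median was 74.6%. Mbp (myelin basic protein, chromosome 18, 82475146 to 82585637) was detected in 55 cells at 429 FPKM, Mobp in 54 at 343 FPKM and Opalin in 29 cells. At least 50% of the list was detected in 46 cells (78.0%, interval 65.3 to 87.7%). Oligodendrocyte precursor genes had a median of 6.78% of cells, from Olig1 in 42 cells to Gpr17 in 2.

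Microglia and astrocyte genes were detected less widely, with 7 of 13 and 8 of 20 members found in at least 50% of cells. The list median was 55.9% over 13 genes, from C1qb (complement, 42 cells, median 100 FPKM) to Tmem119 (14 cells), and at least 50% of the list was detected in 28 cells (47.5%, interval 34.3 to 60.9%). Astrocyte genes had a median of 39.0% over 20 genes. Apoe was detected in 55 cells, Glul (glutamine synthetase) in 54 at 149 FPKM, S100b in 47 and Clu in 45. Aqp4, Gjb6 and Fgfr3 were detected in 13 cells each and Aldh1l1 in 10. Gfap, the astrocyte intermediate filament gene, named outside the rule for named genes, was detected in 34 cells with a median of 4.33 FPKM. At least 50% of the list was detected in 29 cells (49.2%, interval 35.9 to 62.5%). Reactive astrocyte genes had a median of 5.08%, from Serpina3n in 29 cells to Lcn2 in 1. Endothelial and mural genes had a median of 3.39% with Rgs5 the highest in 10 cells, fibroblast and ependymal genes 8.47% with Foxj1 the highest in 13 cells, and erythroid genes 6.78% with Hba-a1 the highest in 9 cells.

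Neuronal and glial genes were found in the same cells. At least 50% of both the neuronal and the oligodendrocyte list was detected in 36 cells, of both the neuronal and the microglia list in 23, and of both the neuronal and the astrocyte list in 29. All 4 lists reached this level in 19 cells. The neuronal list reached it without the oligodendrocyte or microglia list in 9 cells (15.3%, interval 7.22 to 27.0%) and without any of the 3 glial lists in 6 cells (10.2%, interval 3.82 to 20.8%). The oligodendrocyte or microglia list reached it without the neuronal list in 11 cells, and 2 cells reached it for none of the 4. These combinations went with the number of genes detected per cell. The 6 cells with the neuronal list alone had 1097 to 2101 genes, apart from cell 61 with 6168. The 19 cells with all 4 lists had at least 3321 genes. A list that was not reached may therefore reflect few genes detected in part of the cells. Cells 19, 21, 45, 57 and 60 missed the neuronal list with 3465, 7219, 4303, 4149 and 5085 genes. Few genes detected does not account for these cells.

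The GABA synthesis and transport genes Gad1, Gad2 and Slc32a1 were detected in more cells than the 3 vesicular glutamate transporter genes, while the whole GABA and glutamate lists had equal medians of 22.0%. Gad1 (GABA synthesis, chromosome 2, 70553072 to 70602014) was detected in 46 cells with a median of 11.7 FPKM, Gad2 in 45 at 13.0 FPKM and the vesicular GABA transporter gene Slc32a1 in 22. At least 1 of these 3 was detected in 50 cells (84.7%, interval 73.0 to 92.8%), and all 3 in 20 cells. The vesicular glutamate transporter genes were detected in 26 cells (44.1%, interval 31.2 to 57.6%), with Slc17a7 (chromosome 7, 45163949 to 45176142) in 20, Slc17a6 in 11 and Slc17a8 in 2. Every one of those 26 cells also had a GABA gene, where the product of both shares gives 22.0, a value that takes no account of cells differing in depth. GABA genes without glutamate genes were found in 24 cells, glutamate genes without GABA genes in 0, and neither in 9. At an FPKM of 5 the glutamate share was 27.1% and the share with both 23.7%.

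**Figure D4:**
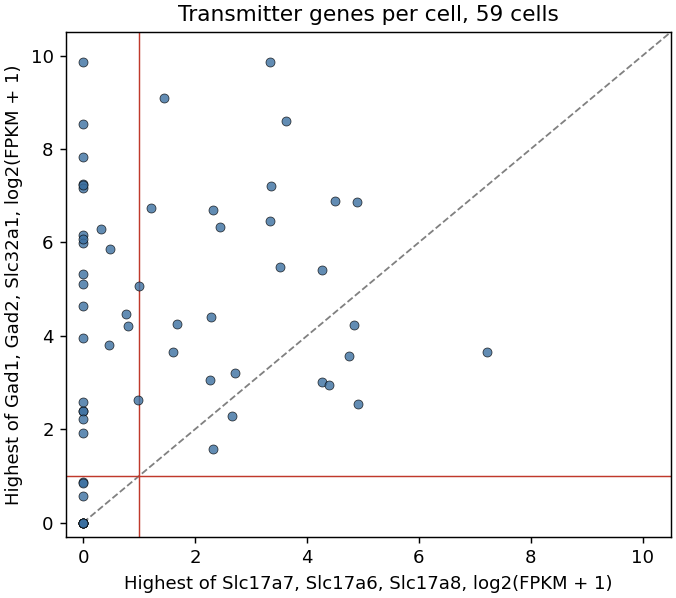
Highest log2(FPKM + 1) of Gad1, Gad2 and Slc32a1 (y axis) against the highest of Slc17a7, Slc17a6 and Slc17a8 (x axis), with 1 point for each of the 59 cells, red lines at an FPKM of 1 and a dashed line where both are equal. No cell lies in the lower right field of glutamate genes alone, and 26 cells lie in the upper right field.

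The lowest of the 10 GABA list genes were the transcription factor genes Dlx2 in 4 cells and Dlx5 in 8. Genes of other transmitter systems were detected in part of the cells, and their defining combinations in few. At least 1 of 4 cholinergic genes was detected in 14 cells, with Lhx8 the highest in 9, and at least 1 of 6 monoaminergic genes in 26 cells, with Ddc the highest in 14. Chat or Slc18a3, cholinergic genes, were detected in 2 cells, and the cholinergic list had a median of 5.08%. Th with Slc6a3 or Slc18a2, dopamine genes, was detected in 1 cell and the serotonin transporter gene Slc6a4 in 1 cell, and the monoaminergic list had a median of 5.93%. The glycine transporter gene Slc6a5, the only member of the glycinergic list, and the serotonin synthesis gene Tph2 were not analysed here.

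Striatal projection neuron genes were detected in part. Ppp1r1b (DARPP-32, a dopamine-regulated phosphatase inhibitor, chromosome 11, 98348404 to 98357796) was detected in 42 cells (71.2%, interval 57.9 to 82.2%), with a median of 19.6 FPKM. Meis2 was detected in 35 cells and Bcl11b and Foxp1 in 31 each, and all 4 genes were found together in 18 cells (30.5%, interval 19.2 to 43.9%). Dopamine receptor genes were detected in fewer cells, with Drd1 without Drd2 in 10, Drd2 without Drd1 in 4, both in 1 and neither in 44. Over the 20 members of the list, 8 were detected in at least 50% of cells, the median was 33.1%, and Gpr6 was the lowest in 4 cells.

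Interneuron and cortical markers were each carried by a few genes. Cck was detected in 37 cells, Sst (somatostatin) in 34, Pvalb (parvalbumin) in 30 and Npy (neuropeptide Y) in 29, against a list median of 12.7% over 14 genes and Chodl in 1 cell. Sst and Npy were found together in 20 cells, and Pvalb, Sst and Ppp1r1b together in 20 cells. The cortical layer list had a median of 22.0% over 11 genes, from Etv1 in 35 cells to Fezf2 and Nxph4 in 4 each. Foxp2 of this list is also in the striatal list.

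Presynaptic genes were the most widely detected of the synapse and excitability genes. Of 14 presynaptic genes, 11 were found in at least 50% of cells, with a median of 73.7%. Vamp2 (synaptobrevin) was detected in 56 cells, Syt1 and Rab3a in 50 each and Stx1a in 14, and Syn1, Snap25 and Syt1 are also in the neuronal list. Postsynaptic genes had a median of 30.5% over 12 genes, from Camk2a in 43 cells to Shank3 in 5.

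Ion channel and receptor genes were detected in fewer cells than presynaptic genes. Voltage-gated sodium channel genes had a median of 38.1% of cells over 8 genes, 2 of which were detected in at least 50% of cells. Potassium channel genes had a median of 32.2% over 15 genes, with Kcna1 in 40 cells and Kcnd3 in 8, and calcium channel genes 16.1% over 10, from Cacnb4 in 32 cells to Cacna1c in 2. Glutamate receptor genes had a median of 37.3% over 11 genes, with the AMPA receptor gene Gria2 the highest in 40 cells and Grik1 the lowest in 12. GABA receptor genes had a median of 38.1% over 12, with Gabbr1 in 43 cells and Gabrb2 in 8. At an FPKM of 5 the medians were 22.9% for sodium, 20.3% for potassium and 6.78% for calcium channels, 22.0% for glutamate receptors and 12.7% for postsynaptic genes. With any FPKM above 0 they were 56.8%, 47.5% and 32.2% for the channels, 54.2% for GABA receptors and 44.9% for postsynaptic genes.

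Of the 20 genes with the most spread between cells for their level, 4 are in the fixed microglia list and 2 in the oligodendrocyte list. Apod (a lipocalin) had the largest excess SD, 1.91 above the trend of 2.84 on the log2 scale, followed by Klk6 (1.74), Ctss (1.73), C1qa (1.73) and Ccl4 (1.67). Cldn11, Mog, Cryab, Cmtm5 and Car2 were also among the 20 highest, as were Tyrobp, C1qb, Ccl3, Il1a, Lyz2, B2m, Ctsz, Serpina3n, Ttr and mt-Tp. Cldn11 and Mog are the oligodendrocyte list members and Ctss, C1qa, C1qb and Tyrobp the microglia list members. Serpina3n is in the fixed reactive astrocyte list and B2m in the housekeeping list. The Spearman correlation between pairs of cells had a median of 0.249 over 1711 pairs, with a range of 0.0201 to 0.642. No 2 cells had the same values.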

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

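The thresholds of 10 recovered fragments and 500000 fragments per cell and the shortened astrocyte list were chosen after the results were seen, and the other alternatives before. Of 197 values of 28 results under alternatives, 179 stayed within the main value's spread, 18 moved and 0 changed sign. Shares of cells and gene counts have no sign to change. The spread was the 95% interval of a share, the quartile range of genes per cell, or the SD of pairwise correlations. It describes counting error or differences between cells, which is a wide yardstick for alternatives that use the same cells. At an FPKM of 5 the share of cells with at least 50% of the astrocyte list was 35.6%, with a vesicular glutamate transporter gene 27.1%, with a GABA gene 72.9% and with both 23.7%. The medians were 22.9% for sodium, 20.3% for potassium and 6.78% for calcium channels, 22.0% for glutamate receptors and 12.7% for postsynaptic genes. With any FPKM above 0 they were 56.8%, 47.5% and 32.2% for the same channels, 44.9% for postsynaptic genes and 54.2% for GABA receptors. These moves come from the threshold itself. In the 46 cells with at least 2000 genes, 89.1% had at least 50% of the oligodendrocyte list and 82.6% had Ppp1r1b, under a filter that itself selects on detection. In the 39 cells with at least 500000 fragments these shares were 82.1% and 76.9%. Without Apoe, Glul, S100b and Clu the neuronal list exceeded the astrocyte list in 86.4% of cells. Without a filter on low genes the median correlation between cells was 0.348; the cause was not tested. The median neuronal minus astrocyte difference ran from 0.21 to 1.86 over the alternatives that kept the astrocyte list, and 15 to 20 of the 20 genes with the most spread were shared. The pseudocount cannot change a rank correlation. Among 320 single genes, 112 fell at an FPKM of 5 and 53 rose with any FPKM above 0. Depth may limit detection in the 20 cells under 500000 fragments, where a gene not detected may be expressed. Without these cells 11 of 320 genes moved, 7 of them upward. No paired analysis was possible because the labels give 1 group.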

Other observations

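The tests of stray single reads, of sequencing depth, of ribosomal and mitochondrial RNA, of the spike-in share and of a glial cell sampled without neuronal RNA were chosen after related results were seen. The others were set before their results. No biological explanation was tested for any pattern, because the labels give 1 group and no control neurons, astrocytes or untreated cells were analysed here.

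Immediate early genes were detected in most cells. The median over 10 genes was 78.0% of cells, with Fos in 57 cells (median 1160 FPKM), Egr1 in 55, Jun in 53 and Junb in 52, while the activity-dependent transcription factor gene Npas4 was detected in 18 and Arc in 22. Stress genes had a median of 64.4% over 8 genes, with the chaperone gene Hsp90aa1 in all 59 cells (median 303 FPKM) and Hspa1b in 4. The housekeeping list had a median of 95.8% over 10 genes, with Ubb in 59 cells and the low-abundance gene Tbp in 11.

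Some genes reached levels in single cells far above their median. The chemokine genes Ccl4 and Ccl3 were detected in 33 and 28 cells with highest values of 53145 and 37735 FPKM, and the cytokine gene Il1a in 23 cells with a highest value of 11666 FPKM. Sst reached 9392 FPKM against a median of 2.45 FPKM, and Th, the dopamine synthesis gene, reached 1866 FPKM with detection in 6 cells. Ttr (transthyretin) was detected in 25 cells with a highest value of 8114 FPKM.

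At least 50% of the oligodendrocyte list was detected in 46 cells and of the microglia list in 28 cells. More than single reads at the threshold lay behind these transcripts. The median oligodendrocyte gene had 10 or more recovered fragments in 68.6% of cells and the median microglia gene in 50.8%. For any off-tissue gene the share was at most 5.08% (upper limit of the interval 14.1%). Recovered fragments may be copies of 1 molecule, and off-tissue genes cannot measure brain RNA carried over between cells, so carry-over stays open. The log2 ratio of a pair of oligodendrocyte genes had a median SD over cells of 1.81, against 3.75 for an oligodendrocyte and a neuronal gene, a quotient of 0.482, and the quotient for microglia genes was 0.476 (1.77 against 3.71). Each glial set thus varied as a unit apart from the neuronal genes, which is what RNA taken up from tissue as a single source may give, but a glial cell sampled together with or in place of the target, or an oligodendrocyte or microglia programme in the cell itself, would give the same. Of the 37 cells in which an oligodendrocyte or microglia list was the highest, 25 (interval 50.2 to 82.0%) still had at least 50% of the neuronal list. Of the other 12, 11 had a neuronal gene at 10 or more recovered fragments. In cells 8, 17, 18, 23, 24, 33, 37 and 58, all 21 neuronal genes were detected. Their neuronal list means were 4.37 to 6.30, against a median of 4.04 over all cells. These cells were picked from the same values because all 21 genes were detected. For them, these levels argue against a glial cell sampled without neuronal RNA, unless the RNA was carried over between cells. The line to the other cells is not sharp. Cells 5, 16 and 49 had neuronal means of 4.73, 4.90 and 4.51 with 17, 19 and 19 neuronal genes detected. In the rest of the 37, detection can rest on 1 fragment and a glial cell's own low expression may add to it. There, a glial cell sampled without neuronal RNA mostly cannot be told apart from a mixture. Cell 53 had 0 neuronal genes detected and an oligodendrocyte mean of 7.38, so it gave no sign of a mixture. Only 519 genes were detected in it. The neuronal mean was also low in cells 21 (0.80) and 40 (0.86), with 7 and 4 neuronal genes detected. Their estimated depths were 2934690 and 2693730 fragments, and their highest list means were 9.71 (microglia) and 10.1 (oligodendrocyte).

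GABA and glutamate genes were found together in 26 cells. If the weaker set were a trace from a second neuron, the levels should lie far apart in most of these cells. The higher level was over 4 times the lower in 17 of the 26 cells (interval 44.3 to 82.8%), with GABA higher in 15 and glutamate higher in 2. That interval includes an even split, so the prediction was not decided. Expression of both sets at unequal levels in the same cell would also put the levels far apart. This comparison therefore cannot tell such expression from a trace of another neuron.

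The number of genes detected differed by a factor of 22.1 between cells, counted on genes with an exon length and any FPKM above 0. Thinning each cell to 10000 recovered fragments left a factor of 14.1 (277 to 3906 genes, quartiles 1303 and 2614), which argues against depth as the whole cause. Thinning to 5000 fragments without Rn18s-rs5 and mitochondrial genes left a factor of 11.5 (227 to 2602 genes, quartiles 1074 and 1944). That argues against those RNAs as the whole cause. Each factor compares only the highest and the lowest cell, and the quartiles lie much closer together. Of the 15 cells with the highest ERCC share, 11 were among the 15 with the fewest genes after thinning, where 3.81 would be by chance. Little starting RNA may therefore contribute, a hypothesis found and tested on the same cells.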
